A study of Homo sapiens with 10 samples.

How the data were processed

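RNA bound by pseudouridine synthase 7 (PUS7) was measured by individual-nucleotide resolution crosslinking and immunoprecipitation (iCLIP) in 10 libraries from established human cell lines. HEK 293T, a transformed embryonic kidney line, had 3 libraries from PUS7 knockout cells carrying FLAG-tagged PUS7 and 3 libraries from PUS7 knockout cells without it. H9, a human embryonic stem cell line, had 2 libraries of each kind. Per the labels' protocols, living cells were crosslinked with UV light of 254 nm at 200 mJ/cm2, the lysates were treated with RNase I, and complexes were pulled down on anti-FLAG beads for 2 h at 4 °C. The knockout libraries went through the same anti-FLAG pull-down without a tagged PUS7 and served as mock controls. Reads of 50 cycles were obtained on a MiSeq. Bowtie, SAMtools, bedtools and the genome build hg38 are named in the submitters' processing notes, without versions or roles. The peak caller is not given in the sources used here. Per the labels each replicate took the cells of 2 plates of 15 cm, but whether these were grown apart, at other passages or on other days, is not stated, so p-values measure only the spread between these samples.

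Each library had a table with 631 tRNA rows and 1 row for unmapped reads. The values the authors deposited in these tables are neither counts nor a normalized unit. In all 10 tables every whole number from 1 to the maximum occurred without a gap, with 335 to 414 distinct values in FLAG-PUS7 libraries and 6 to 102 in knockout libraries. This is the form left when text values are replaced by level numbers, which follow the alphabetical order of the text and not its size. The first H9 knockout table held only 6 values and placed every tRNA row at the lowest level of its text width, which sorted the rows into 4 main width classes, numbered from 1 for the narrowest. In the 9 other tables, 381 values were shared by several rows and 0 of them mixed rows of different width classes. After shuffling the classes in 100 draws, the lowest number of mixed values, summed over the 9 tables, was 272. The lowest run of levels was read as no reads, and every higher level as at least 1 read. Reading simulated tables of 631 rows back in this way gave 0% wrong entries, with width classes known and a simulated empty library set to no reads. The simulated tables were built by the same coding rule, so that this cannot show whether the deposited tables follow it. Only detection per row could be recovered, so that no amount, fold change or sequencing depth is given for tRNAs. Detection was chosen as the readout after the tables were seen. The count tests fixed before the data were examined, with their normalizations, filters, set tests and isotype shares, were not run because they need counts.

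Rows were grouped into 76 families by isotype and anticodon, and 57 families had a row detected in at least 1 library. The share of a family's rows detected was compared between FLAG-PUS7 and knockout libraries by an exact two-sided permutation test over all 120 assignments of the FLAG-PUS7 label within cell lines, with both lines weighted equally. The smallest p this test can give is 0.0167. Within 293T alone the smallest p is 0.1 and within H9 alone 0.333, so that neither line can pass 0.05 by itself. P-values were adjusted by the Benjamini-Hochberg method. Families at the smallest p pass by themselves only if at least 20 of 57 reach it, and single rows only if at least 172 of 513 do. In simulated data with 40 of 57 families truly different, 99% of them were called and 0.369% of the calls were false. A yield shared by all families of a library was not simulated, although the knockout libraries ranged from 0 to 232 detected rows. These rates therefore need not hold here. The same test on 500 single simulated rows called 0% of 200 true differences, so that it had no power for single rows. The difference between lines was tested by permuting the line labels within genotype, with 100 assignments.

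Lists of isotypes were fixed before the data were examined: Ala, Cys and Val; Tyr; the isotypes Asp, Glu, Gln, Gly and His; families with introns (Tyr, Arg-TCT, Ile-TAT and Leu-CAA); initiator Met; Ser, Leu and SeC; mitochondrial-type rows, which are those with an nm or nmt prefix; and undetermined or suppressor rows. Lists and a motif that need tRNA or genome sequence were not analysed here. Named families are those past the threshold and higher in every FLAG-PUS7 library, the 10 with the largest difference first, together with every isotype in the lists. Families with the largest share of reads, which the same rule names, were not named because no amounts are known. Because only the test over both lines can pass the threshold, the rule was applied to that test. Of the 631 rows, 457 matched a symbol in the RefSeq gene table of GRCh38.p14, 408 of them tRNA genes and 49 pseudogenes, and coordinates are 1-based on that build.

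Peak lists were deposited for the 5 FLAG-PUS7 libraries only and were called per library. Each list gives positions in bins of 200 bases with adjoining bins merged, a strand, a signal, a p-value and a further value. The deposited signal is a whole number at single bins and a mean over merged bins, with no scaling for depth. The authors' p-value reached at most 0.0486 in any list. The last deposited column is the natural log of a whole number at single bins, called here the second count, and its origin is not given in the sources used here. Peak signals are the authors' own and were not tested between groups. They rank peaks within a list, order loci by their sum over lists, where lists with higher signals weigh more, and give a ratio between the H9 lists in the closing section. Peaks were assigned to RefSeq genes by an overlap of at least 1 base without regard to strand, since the gene table carries none, with small RNA classes given priority over the genes that host them. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Peaks of different libraries were called shared when they overlapped by at least 1 base on the same strand. Named loci are the 5 highest peaks of each library and the first 20 loci by number of libraries and then by summed signal. Alternatives were leaving out each library, using replicate numbers as a block, a stricter detection level, only RefSeq tRNA genes, peaks at or above the median signal of their list, and other overlap rules. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.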

Results

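The data comprised 10 iCLIP libraries, which record RNA crosslinked to a protein in living cells. The protein was PUS7, an enzyme that converts uridine to pseudouridine in tRNA and mRNA, carried with a FLAG tag in PUS7 knockout cells. There were 3 FLAG-PUS7 and 3 knockout libraries in 293T, and 2 and 2 in H9 embryonic stem cells. Because the tRNA tables hold level numbers in place of read counts, a tRNA row is described only as detected, with at least 1 read, or not detected. The sequencing depth of the libraries is unknown. The level of PUS7 itself was not analysed here.

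The first comparison asked which tRNAs came down with FLAG-PUS7 and not in the mock pull-down. FLAG-PUS7 libraries held reads from nearly every row matched to a RefSeq tRNA gene, whereas knockout libraries held reads from fewer of them. In 293T, 468.7 ± 10.1 (SD, n = 3) of the 631 rows were detected with FLAG-PUS7 and 168 ± 55.5 (SD, n = 3) in the knockout. In H9 the FLAG-PUS7 libraries detected 479 and 472 rows, and the knockout libraries 0 and 232. The mean difference over both lines was 330.1 rows (exact two-sided permutation p = 0.0167, the smallest possible). The differences were 300.7 rows in 293T and 359.5 rows in H9, each at the smallest p its size allows (exact permutation p = 0.1 in 293T and 0.333 in H9). The width classes came from the first H9 knockout table itself, so that its 0 detected rows follow from how the levels were read. They can mean a library without tRNA reads or a table that was not filled. Without this table, the difference over both lines was 272.1 rows and remained at the smallest possible exact permutation p of 0.0167.

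**Figure D1:**
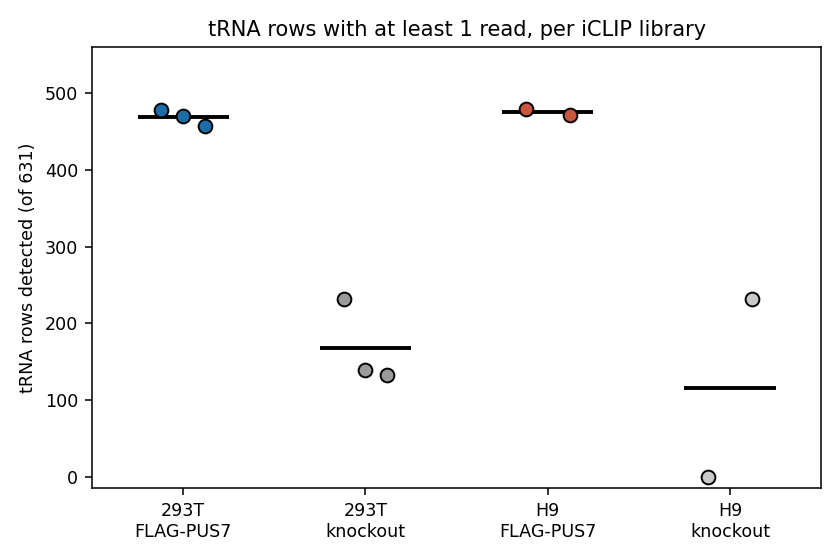
Number of tRNA rows with at least 1 read (vertical axis, of 631 rows) in each library of the 4 groups. Points are libraries and lines are group means; the 5 FLAG-PUS7 libraries lie between 458 and 479, and the 5 knockout libraries between 0 and 232.

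Among the 408 rows matched to a RefSeq tRNA gene, 97.4% ± 0.374 (SD, n = 3) were detected in 293T with FLAG-PUS7 and 39.1% ± 13.1 (SD, n = 3) in the 293T knockout. In H9 the FLAG-PUS7 libraries detected 97.5% and 97.3% of them, and the knockout libraries 0% and 53.4%. The 49 rows matched to tRNA pseudogenes were seldom detected, with 19.7% ± 2.36 (SD, n = 3) in 293T with FLAG-PUS7 and 0% in each 293T knockout library. Across all libraries, 425 rows were detected in all 5 FLAG-PUS7 libraries. Of these, 128 were in no knockout library, and 71 were in each of the 4 knockout libraries with any tRNA row. No row was detected in a knockout library without also being detected in a FLAG-PUS7 library. Tested row by row, 0 of 513 rows passed the adjusted threshold (exact permutation test, lowest adjusted p = 0.0668), and 128 rows had an unadjusted p under 0.05.

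At the level of anticodon families, 45 of 57 rose in the share of rows detected with FLAG-PUS7 and 0 fell (exact permutation test, adjusted p from 0.0221 to 0.0422). All 45 were higher in every FLAG-PUS7 library than in the mean of its knockouts. Families that did not pass, such as Leu-TAG and Glu-CTC, also met this condition, so that it does not set the 45 apart. Pro-CGG, with 4 rows, was detected in full in all 5 FLAG-PUS7 libraries and in 0 rows of any knockout library, a difference of 100 percentage points. Its gene copies include TRP-CGG1-1 on chromosome 1 at 167714725 to 167714796 and TRP-CGG2-1 on chromosome 6 at 27091742 to 27091813. Gly-CAC with 2 rows, Ser-ACT with 1 row and the suppressor family Sup-TTA with 1 row showed the same difference. Ser-ACT and Sup-TTA, being single rows, passed only in the adjustment over 57 families and not in that over 513 rows. Pro-TGG differed by 95.2 points, Thr-AGT and Ile-TAT by 93.3, Thr-TGT by 93.1, Ala-CGC by 90 and Pro-AGG by 88.3, each at an adjusted p of 0.0221 by the exact permutation test. Among the smaller differences, Asp-GTC passed with 31.2 points, or 9.38 points without the first H9 knockout library, and each 293T knockout library detected 81.2% of its 16 rows. Leu-TAG (22.9 points, adjusted p = 0.518) and Glu-CTC (27.5 points, adjusted p = 0.152) did not pass the exact permutation test, and differed by 4.17 and 7.5 points without the first H9 knockout library. Without the first H9 knockout library 43 of 57 families passed, all 43 among the 45. Leaving out either H9 FLAG-PUS7 library reduced the number to 23.

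The fixed lists separated by how much of them the knockout libraries held. Of the 125 Ala, Cys and Val rows, the isotypes that the study itself singles out and so no independent evidence, 80.3% ± 3.61 (SD, n = 3) were detected in 293T with FLAG-PUS7 and 13.1% ± 11.04 (SD, n = 3) in the knockout. In H9 the mean with FLAG-PUS7 was 78.8% ± 2.83 (SD, n = 2), and the knockout libraries held 0% and 18.4%. The list rose by 68.4 points (exact permutation test, adjusted p = 0.0222). In this list and in the other lists that passed, each of the 5 FLAG-PUS7 libraries was higher than every knockout library of its line. The rise of the Ala, Cys and Val list was 16.4 points more than that of the other rows without an nm or nmt prefix. This excess did not pass after adjustment (exact permutation test, adjusted p = 0.0667). Without the first H9 knockout library the excess was 23 points and passed (exact permutation test, adjusted p = 0.0222). By isotype the excess was 16.9 points for Ala (unadjusted exact permutation p = 0.0333) and 21.5 points for Cys (p = 0.05). Without that library the excess was 26.6 and 32.0 points (exact permutation p = 0.0167 for both). Val had 2.31 points, or -2.34 points without the library (exact permutation p = 0.65 for both). The isotypes were not tested against each other. Adjusted over the list alone, 45 of its 113 tested rows passed, against 0 over all rows. Of the 25 Cys rows detected in all FLAG-PUS7 libraries, 24 were in no knockout library. The same count was 15 of 26 for Ala and 6 of 31 for Val. In 293T, Cys rows were detected at 79.3% ± 4.13 (SD, n = 3) with FLAG-PUS7 and 0.901% ± 1.56 (SD, n = 3) in the knockout. Of the 37 Cys rows, 24 were in width class 1 and 13 in class 2, where the knockout libraries detected at most 1.21% and 33.1% of all rows of the class.

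Tyr rows, whose precursor is a known target of the yeast enzyme at the anticodon, rose by 64.2 points (exact permutation test, adjusted p = 0.0222), and 5 of 13 tested rows passed adjusted over the list alone. The intron-containing families rose by 64.6 points (exact permutation test, adjusted p = 0.0222), with 11 of 30 rows passing adjusted over the list alone. Their excess over the other rows was 8.98 points for Tyr and 9.68 points for the intron families and did not pass (exact permutation test, adjusted p = 0.590 and 0.111). Without the first H9 knockout library it was 19.1 and 17.2 points and passed (exact permutation test, adjusted p = 0.0381 and 0.0222). Asp, Glu, Gln, Gly and His, isotypes in which PUS7-type pseudouridine is known near the D arm, rose by 41.8 points (exact permutation test, adjusted p = 0.0222), or by 26.8 points without the first H9 knockout library. Their rise was smaller than that of the other rows, by a list-minus-other difference of -17.5 points (exact permutation test, adjusted p = 0.0444). The 293T knockout libraries held 44.1% ± 7.59 (SD, n = 3) of these rows, and 12 of the 93 detected in all FLAG-PUS7 libraries were in no knockout library. By isotype, that count was 1 of 15 for Asp, 1 of 18 for Glu, 1 of 17 for Gln, 8 of 33 for Gly and 1 of 10 for His. Adjusted over the list alone, 0 of 108 rows passed, with 12 at an unadjusted p under 0.05. Of all rows in width class 4, the knockout libraries with any tRNA row detected 66.3% to 96.5%, which left little room to rise. This class held 11 of 16 Asp, 9 of 10 His and 13 of 39 Gly rows, but 2 of 29 Glu and 0 of 33 Gln rows.

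Ser, Leu and SeC, the tRNAs with a long variable arm, rose by 42 points (exact permutation test, adjusted p = 0.0222), with a list-minus-other difference of -15.4 points that did not pass (adjusted p = 0.08). Without the first H9 knockout library the list rose by 25.3 points, and the list-minus-other difference was -23.1 points and passed (exact permutation test, adjusted p = 0.0222). Adjusted over the list alone, 0 of 63 rows passed, with 5 at an unadjusted p under 0.05. Width class 4, with little room to rise, held 13 of 28 Ser, 14 of 41 Leu and 0 of 3 SeC rows. Of their rows detected in all FLAG-PUS7 libraries, 2 of 27 Ser rows, 3 of 31 Leu rows and 0 of 1 SeC rows were in no knockout library. Leaving out either H9 FLAG-PUS7 library ended the calls of this list and of the Asp, Glu, Gln, Gly and His list, at an unadjusted exact permutation p of 0.0833 each. Initiator Met differed by 54.2 points (exact permutation test, adjusted p = 0.05, not under the threshold), and 0 of 9 rows passed adjusted over the list alone. The second H9 knockout library detected 9 of the 10 initiator rows, as did every FLAG-PUS7 library, and without it the difference was 76.7 points at an unadjusted exact permutation p of 0.0167. Without the first H9 knockout library it was 31.7 points (exact permutation test, adjusted p = 0.114). Of the 41 rows with an nm or nmt prefix, 4.88% ± 2.44 (SD, n = 3) were detected in 293T with FLAG-PUS7, and the difference of 6.5 points did not pass (exact permutation test, adjusted p = 0.05). Of 14 undetermined or suppressor rows, 2 were detected in all 5 FLAG-PUS7 libraries and in no knockout library (14.3 points, exact permutation test, adjusted p = 0.0222), and both passed adjusted over the list alone. Relative to the other rows both of these groups were lower in difference, by a list-minus-other value of -49.0 points for nm and nmt rows and -42.0 points for undetermined or suppressor rows (exact permutation test, adjusted p = 0.0444 for both).

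**Figure D2:**
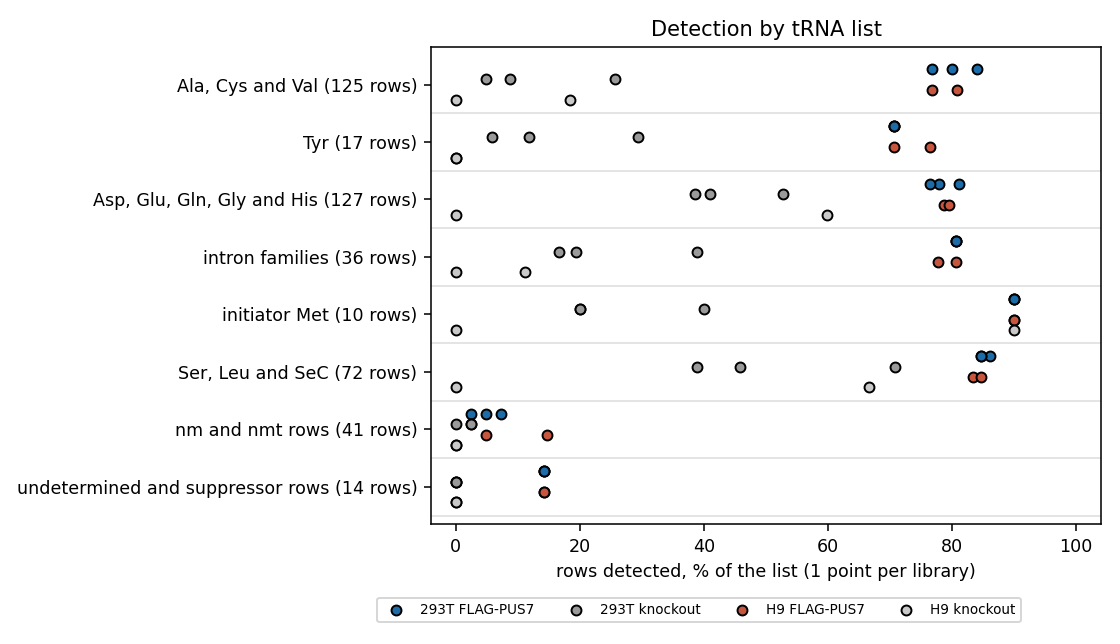
Share of rows detected (horizontal axis, percent of the list) in each fixed tRNA list, with 1 point per library and colours for the 4 groups. The 293T knockout mean is 13.1% for Ala, Cys and Val and 51.9% for Ser, Leu and SeC, and the second H9 knockout library equals the FLAG-PUS7 libraries at 90% for initiator Met.

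The comparison of H9 with 293T asked whether the tRNAs recovered differ between stem cells and kidney cells. The FLAG-PUS7 libraries of the lines shared most detected rows: 425 rows were in all 5, 5 were in both H9 and no 293T FLAG-PUS7 library, and 3 were in all 3 293T and no H9 FLAG-PUS7 library. Among these 8 rows, named after their values were seen, were TRC-GCA15-1 in H9 (chromosome 7, 149584725 to 149584796), TRC-GCA16-1 in 293T (chromosome 7, 149546540 to 149546611) and the pseudogene TRV-CAC11-2 in 293T. Each FLAG-PUS7 library detected 97.1% to 97.8% of the 408 rows matched to a RefSeq tRNA gene, so that detection lay near its ceiling and left little room for the lines to differ. The difference in effect, H9 minus 293T, was 58.8 rows (exact two-sided permutation p = 0.56, smallest possible 0.01). Its value depended on which knockout library was kept: it was -57.2 rows without the first H9 knockout library, 174.8 rows without the second (exact permutation p = 0.05), and 26.8 rows without the first 293T knockout library. Of 57 families, 0 differed between lines after adjustment and 0 at an unadjusted exact permutation p under 0.05.

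Peak lists addressed which other RNAs FLAG-PUS7 contacted. They existed for FLAG-PUS7 libraries only, so no peak list of a mock control could be set beside them. Whether their second count stems from a mock library is not stated in the sources used here. The 293T lists held 120, 85 and 39 peaks, and the H9 lists 1605 and 199. Although the lists are named as being without tRNA, tRNA genes were the largest class of every list but the first of H9. In 293T, peaks at a tRNA gene made up 41.7% (95% interval 32.7 to 51.0), 48.2% (37.3 to 59.3) and 46.2% (30.1 to 62.8) of the lists. In H9 they made up 7.1% (5.89 to 8.47) and 27.6% (21.5 to 34.4). In the first 293T list, 27 of 50 such peaks contained the whole tRNA gene (54%, 95% interval 39.3 to 68.2). The others held part of it. Among all 443 RefSeq tRNA genes, 63.9% lie within a single bin, a value inside the interval of every list. The count therefore shows no excess over what the bins alone give. Whether the reads lay in the tRNA or beside it cannot be told from bins. Of the signal summed over all peaks, tRNA genes carried 51.3%, 61.6% and 62.6% in 293T, in 53 of 132, 44 of 89 and 20 of 42 bins. In H9 they carried 24.7% and 53.6%, in 129 of 1826 and 59 of 224 bins. The first H9 list was dominated in number by 875 peaks in protein-coding genes, 54.5% (52.0 to 56.97), which had a median signal of 3 and carried 23.9% of the signal.

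**Figure D3:**
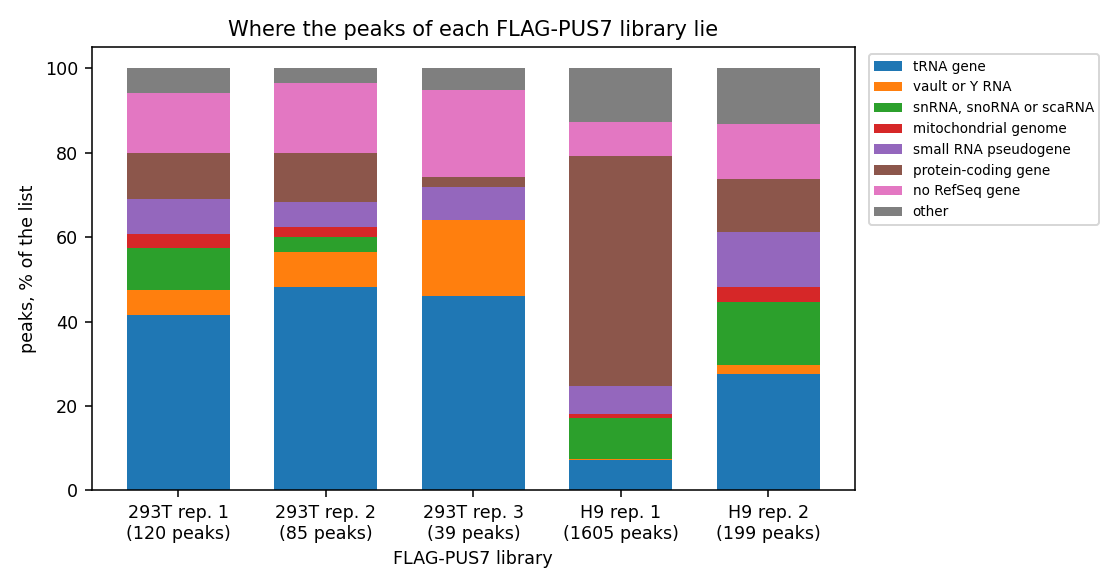
Share of peaks (vertical axis, percent of each list) by the RefSeq gene class they overlap, with 1 bar per FLAG-PUS7 library. tRNA genes make up 41.7% to 48.2% in the 293T lists, while protein-coding genes make up 54.5% in the first H9 list.

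Most of the strongest peaks recurred between libraries. The peak at the valine tRNA gene TRV-CAC3-1 (chromosome 19, 4724401 to 4724800, minus strand) was the highest of 4 of the 5 lists and among the 3 highest of the first 293T list. Its signal was 634, 923.5 and 675.5 in 293T and 416 and 500.5 in H9. Among the 5 highest peaks of each list it had the highest of the authors' p-values, whose test is not given in the sources used here. These were 0.000773 in the first 293T list and 0.00558 in the first H9 list. The glycine gene TRG-CCC2-2 (chromosome 16, 636601 to 636800) was among the 3 highest in each 293T list, at 785, 608 and 472, and had signals of 358 and 145 in H9. The leucine gene TRL-CAG2-1 (chromosome 16, 57300001 to 57300200) had 334, 395 and 235 in 293T and 320 and 212 in H9. RNY5, a Y RNA of the Ro ribonucleoprotein (chromosome 7, 148941401 to 148941600), led the first 293T list with a signal of 879, with 446 and 213 in the other 293T lists and 113 and 63 in H9. The vault RNA VTRNA1-2 (chromosome 5, 140718801 to 140719000) had 492, 391 and 334 in 293T. A further glycine gene, TRG-CCC2-1 (chromosome 2, 70248801 to 70249200), had 388.5, 315 and 233 in 293T and 218.5 and 90.5 in H9. A locus without a RefSeq gene on chromosome 2 (13924001 to 13924200, plus strand) had 367, 676 and 371 in 293T and 25 and 29 in H9. In H9, the isoleucine genes TRI-AAT7-2 (chromosome 6, 26780601 to 26780800) and TRI-AAT7-1 (chromosome 6, 26720801 to 26721000) ranked high, with 340 and 372 at the first and 332 and 342 at the second. In 293T, TRI-AAT7-1 had 10 and 23 in the first and second lists and no peak in the third, and TRI-AAT7-2 had no peak. TRN-GTT6-1 (chromosome 1, 143735801 to 143736000) had 264 in the second H9 list and no peak in any other list. At Y RNA peaks the median second count was 31.5 beside a median signal of 49 in the second H9 list, and 0 beside 57 in the first. At vault RNA peaks it was 8.58 beside 11.25 in the second H9 list, and 2 beside 26.5 in the first. In the 293T lists it was at most 3 at either class. Signals are not scaled for depth, so that levels of different libraries are given side by side without a test.

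Over all lists, peaks merged into 1619 loci, of which 225 were in at least 2 libraries and 32 in all 5. Of these 32, 20 lay at tRNA genes, 2 at vault RNA genes, 2 at Y RNA genes and 1 at a small RNA pseudogene, 6 had no RefSeq gene, and 1 lay on sequence not annotated here. The vault RNA VTRNA1-1 had 274, 194 and 167 in 293T and 38 and 16 in H9, and RNY1 had 35, 65 and 39 in 293T and 103 and 35 in H9. Other members of the first 20 were the asparagine genes TRN-GTT9-1 and TRN-GTT2-4, the glycine genes TRG-TCC2-6, TRG-CCC1-1 and TRG-CCC1-2, and TRL-TAA4-1, TRK-CTT2-2, TRS-GCT6-1 and TRH-GTG1-1. The pseudogene TRE-CTC9-1 (chromosome 2, 150362801 to 150363000) had 69, 89 and 37 in 293T and 244 and 180 in H9. A locus on chromosome X (47802601 to 47802800) had no RefSeq gene, and another on chromosome 5 (181173801 to 181174000) lay within 200 bases of TRL-AAG1-3. Of the tRNA loci of an isotype, those in at least 2 libraries were 9 of 13 for Asn, 7 of 12 for Gly and 7 of 11 for Thr. For Val they were 4 of 4, for Ala 2 of 5 and for Cys 0 of 2. All 39 peaks of the third 293T list overlapped a peak of the first, and 194 of the 199 peaks of the second H9 list overlapped a peak of the first (97.5%, 94.2 to 99.2). In the reverse direction, 190 of the 1605 peaks of the first H9 list were shared (11.8%, 10.3 to 13.5). Overlap expected by chance was not modelled.

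**Figure D4:**
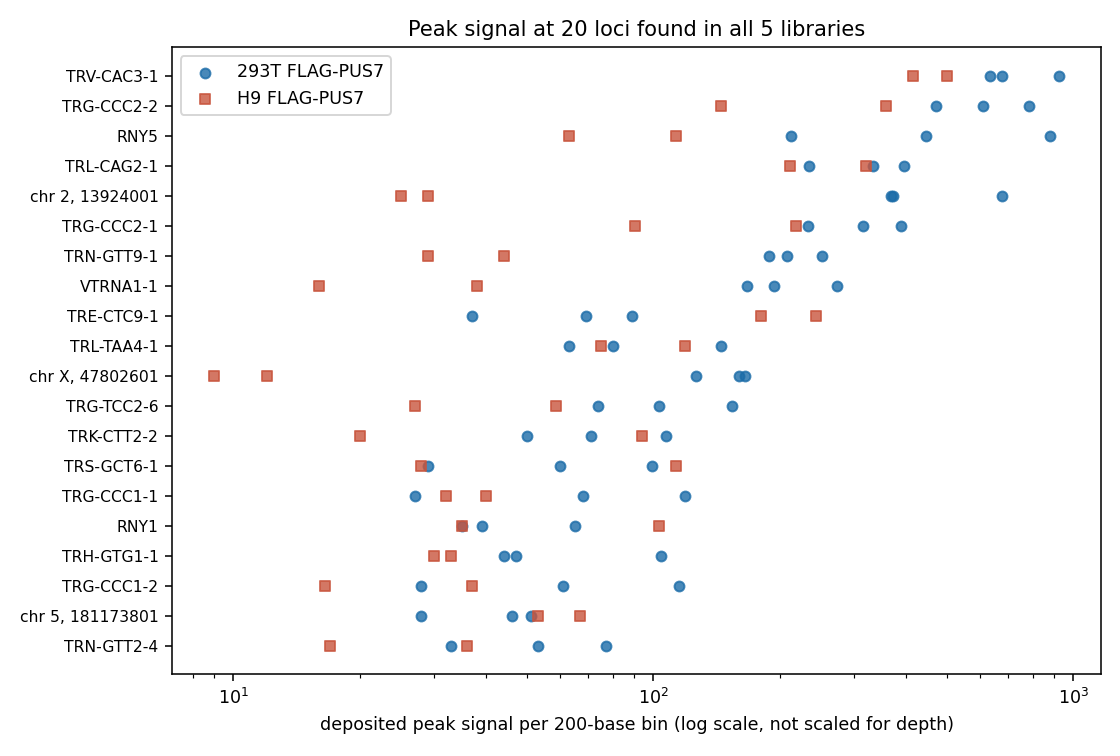
Deposited peak signal per 200-base bin (horizontal log axis, not scaled for depth) at the first 20 loci found in all 5 FLAG-PUS7 libraries, with circles for 293T and squares for H9. TRV-CAC3-1 spans 416 to 923.5, and the chromosome 2 locus without a RefSeq gene spans 25 to 676.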

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

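Of the tests in this part, those of the number of reads and of the second count in H9, and that of a background library, were chosen after the results were seen; the others were fixed before them. The use of intervals to read the H9 ratios, and of only those lists that hold snRNA, rRNA or mitochondrial peaks, was settled after the values were seen.

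Each peak list carries a second count that no comparison above uses. It exceeded 3, the limit that a count of 0 allows, at 18, 8 and 3 peaks of the 293T lists and at 101 and 103 peaks of the H9 lists. It was not a rescaled copy of the signal: the highest Spearman's rho of signal and second count across the peaks of a list was 0.474, and peaks are not independent replicates. The third 293T list had no snRNA, rRNA or mitochondrial peak. In 4 of the 4 other lists, the median second count was higher at these peaks than at tRNA-gene peaks, where it was 0. In the second H9 list the medians were 14 and 0. This is consistent with the hypothesis of a background library, such as a knockout pull-down, as its source, but the sources used here do not state one, and no biological explanation was tested.

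The first H9 FLAG-PUS7 list held 8.07 times the peaks of the second. Counting only peaks at or above 6, the lowest signal in the second list, left 401 against 199 peaks. The ratio fell from 8.07 to 2.02 (95% interval 1.70 to 2.40), so that peaks below this floor made up most of the difference. A lower signal floor alone did not remove the difference. At 137 single-bin peaks in both lists the median ratio of signals, first over second, was 1.5 (95% interval 1.38 to 1.69), which lies on both sides of the bound of 1.5 and leaves more reads in the first library open. At 65 such peaks with a second count above 0 in both lists, the median ratio of second counts was 0.444 (95% interval 0.389 to 0.516). A lower second count behind the first list may therefore be part of the cause, and the design offers no biological contrast between replicates.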

How the results depend on the processing

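Alternatives numbered 179 over 20 results, of which 156 were planned and 23 were chosen after seeing the data (the stricter detection level, RefSeq tRNA genes only, and peaks within 200 bases of a tRNA gene). 156 kept their direction and their side of the threshold or, for values with no test, stayed within their spread and, for counts, within 1.5 times; sizes could still move, as the ranges show. Leaving out each library in turn moved the row difference between 283.2 and 332.7 in 293T, 243.5 and 475.5 in H9, and 272.1 and 388.1 over both lines. It moved the number of families past the threshold between 23 and 49, and the H9 minus 293T difference between -57.2 and 174.8 rows; the negative value, without the first H9 knockout library, reversed the sign. List differences ranged from 63.8 to 73 points for Ala, Cys and Val, 61.8 to 67.6 for Tyr, 26.8 to 56.8 for Asp, Glu, Gln, Gly and His, 61.8 to 68.1 for the intron families, 31.7 to 76.7 for initiator Met, 25.3 to 58.7 for Ser, Leu and SeC, and 4.07 to 8.94 for nm and nmt rows. Calls of the list that starts with Asp and of Ser, Leu and SeC were lost without either H9 FLAG-PUS7 library; initiator Met passed without the second H9 knockout library, and nm and nmt rows without the first 293T FLAG-PUS7 library. The cause was not tested.

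Correlations of deviations for equal replicate numbers were -0.0245, 0.0369 and -0.00626 in 293T and 0.0341 in H9. With 2 H9 libraries of each kind, unequal numbers give the mirrored value by construction. FLAG-PUS7 detection also lay near its ceiling, so that the check cannot settle whether replicate numbers pair the samples. With the replicate number as a block, the smallest exact p over 5 pairs is 0.0625, so that no result can pass. The block gave 324.2 rows over both lines, 0 families, and 68.2 points for Ala, Cys and Val, 62.4 for Tyr, 40.3 for Asp, Glu, Gln, Gly and His, 62.8 for the intron families, 40.3 for Ser, Leu and SeC and 14.3 for undetermined or suppressor rows.

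Counting peaks within 200 bases of a tRNA gene raised the tRNA share to 52.5%, 61.2% and 59.0% in the 293T lists and to 8.66% and 34.7% in H9. Loci in all 5 libraries fell from 32 to 15 among peaks at or above the median signal, by construction from fewer peaks; without 1 library, 32 to 61 loci were in all of the other 4. Count normalizations, count filters, log totals, set tests and motif windows were not run, because the tables hold no counts and no genome sequence was used here.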

Other observations

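The test of other splits of the samples was fixed before its result was seen, and the tests on knockout detection and on width classes were chosen after it; how to read the ratio for Ala, Cys and Val was settled after its values were seen.

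Peaks in both H9 libraries and in no 293T library numbered 106 loci, against 1 locus in all 3 293T libraries and no H9 library. These were taken from 190 loci in both H9 lists and 38 loci in all 3 293T lists. The lowest listed signal was 9, 13 and 22 in the 293T lists and 3 and 6 in the H9 lists. The 2 counts are therefore not on equal terms. The H9 group held 13 loci at snoRNA or scaRNA genes, 6 at snRNA genes, 21 at small RNA pseudogenes, 19 at protein-coding genes, 16 at tRNA genes and 10 without a RefSeq gene. Its strongest members were TRI-AAT7-2, with signals of 340 and 372, and the U2 pseudogenes RNU2-70P (91 and 64) and RNU2-64P (90 and 65). Related genes did have 293T peaks. TRI-AAT7-1 had 10 and 23 in the first and second 293T lists, beside 332 and 342 in H9. The U2 gene RNU2-2 had 60 in the first 293T list, beside 98 and 67 in H9. Whether reads are shared between such copies was not analysed here. The U2 pseudogenes, RNU2-2 and the genes that follow were chosen for naming after their values were seen. RN7SK, the RNA that holds the elongation factor P-TEFb inactive, had 64 and 28, and the box C/D gene SNORD3A had 44.5 and 28. At these 4 loci the second count exceeded the signal in the second H9 list, with 106 at RNU2-70P, 77 at RNU2-64P, 67 at RN7SK and 41 at SNORD3A. In the first H9 list it was below the signal at all 4, with 23, 36, 6.16 and 9.33 in the same order. Medians over the loci of this group follow for small RNA pseudogenes, snRNA genes and snoRNA or scaRNA genes, in this order. In the second H9 list the median second counts were 10, 9 and 6, beside median signals of 10, 9.5 and 7. In the first H9 list the medians were 3, 4.5 and 3 beside signals of 13, 19.5 and 18.5. At its tRNA genes the median second count was 0 in both lists, beside median signals of 9 and 9.5. The single 293T locus was VTRNA1-2, absent even from the H9 list of 1605 peaks, while the neighbouring VTRNA1-1 had peaks in all 5 lists. Whether a peak is listed depends on each list's own threshold, and the difference between lines was not tested.

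The 45 families past the threshold set the real split of the libraries apart. Of 60 splits within cell lines, 1, the real one, gave as many, and the highest of the others gave 0. The family p-values come from the same splits, so that this count restates them, is no separate evidence and cannot by itself exclude chance.

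Families differed in how much of them the knockout libraries held, for example a mean of 0.901% of Cys rows and 81.2% of Asp rows in 293T, and one hypothesis is a low read yield in the mock pull-down, which leaves only the most abundant tRNAs detected. In all 4 knockout libraries with any tRNA row, the share detected rose over the 4 text-width classes. In the first 293T knockout library, for example, it rose from 1.21% to 96.5%. Low yield would give such a rise if the class follows a row's amount. The first 293T FLAG-PUS7 library also detected 98 of 248 rows in class 1 and 86 of 86 in class 4. A rise over classes was therefore not particular to the knockout libraries and does not by itself show low yield. In the first 293T FLAG-PUS7 library, 90.8% of the detected rows in class 1 shared a level with another row and 6.98% of those in class 4, as small numbers would coincide more often; 1 of the 382 rows in classes 2 to 4, Cys-ACA, was detected in no library. For the further hypothesis that Ala, Cys and Val rows are scarcer in the mock background than their width class alone would give, observed over expected rows were 0.972, 0.283 and 0.603 in the 293T knockout libraries and 0.633 in the second H9 knockout library. The library at 0.972 met the bound set against this hypothesis, but a single library cannot exclude it, so that it stays open.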
